A study of Mus musculus with 6 samples.

How the data were processed

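Bulk polyA RNA sequencing was made from the livers of 3 endothelial Sting knockout mice and 3 Cre-negative littermates, all on the same diet. The deposited table held 21956 genes with a value in 2 units for each library. The estimated counts per gene and the TPM values were made by the authors; per the submitters' processing notes the tools were fastp 0.23.2, HISAT2 2.2.1, RSEM 1.3.3 and DESeq2 1.38.3, on GRCm38, with no roles or order given. The annotation release and any filter on genes are not given in the sources used here. Per the labels the libraries were strand-specific; whether counting used the strand is not given, so that overlapping antisense genes stay uncertain, as do near-identical families such as Mup and Cyp genes.

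The estimated counts as deposited were not normalized, and 6.93% of the values were not whole. They were rounded to whole numbers before testing. The deposited TPM values are scaled to gene length and to a fixed total, and were used for an alternative and for levels. Gene positions came from GENCODE M21 on GRCm38, in which 21852 of the table's identifiers were found. Library totals ranged from 16704664 to 21025461 counts. The 3 libraries of a group were described as separate animals. No pair of libraries within a group was close enough in counts to be a repeat, and pairs across the groups were not compared in this way.

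The knockout was compared with the control in edgeR 4.0.16 with the quasi-likelihood test (TMM scaling, filterByExpr, robust fit, prior count 2 for log2 CPM) and Benjamini-Hochberg adjustment at 0.05, which left 13197 genes. CPM values with their SD used TMM-scaled library sizes, except the summed CPM of a marker list, which used total counts. The standard error of a log2 fold change was derived from the fold change and its F statistic. The 40 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members of a list were also adjusted over the list alone. The genes named are Sting1, the 10 with the smallest p in each direction because fewer than 5 passed, and up to 4 members with the smallest p of each list; Alb, Mki67, Bmal1, Clock, Cdkn1a and Sgk1 lie outside that rule and were chosen after their values were seen. Not every gene that the rule allows is reported here. The design, the lists, this rule and most alternatives were fixed before the data were examined.

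Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, other scalings and filters, a replicate block, each library left out in turn, and limma on log2(TPM + 1) and log2(TPM + 0.1). Camera on 2748 annotation terms of the table was added after seeing the data, as was the attention given to the fit without control replicate 2. The main test of annotation terms was not run, since it needed 10 called genes in a direction. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.

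The fits were tested on simulated data: counts for 13091 genes were drawn from the means, library sizes and dispersions of the knockout and control libraries, with 200 genes changed. edgeR recovered 64% of the genes changed by 2-fold and 99% of those changed by 4-fold in this comparison, with 16 false calls among 179. DESeq2 recovered 75% and 99%, with 34 false calls among 208. The share of false calls lay above the nominal level in both tools. The changed genes were taken only from genes with higher mean counts, and all simulated libraries shared the same mean profile. The recovered shares therefore do not extend to genes with low counts or to a library that stands apart. In a list test over 13093 genes, a 1.5-fold shift of the 22 proliferation genes gave a camera adjusted p of 7.98e-19 and of 0.0208 with an estimated correlation, and 1 of the other lists was called. Simulated genes were drawn independently, whereas the real proliferation list had an estimated correlation of 0.72. The simulation therefore cannot show what camera with an estimated correlation detects in these libraries.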

Results

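Messenger RNA was measured by bulk sequencing in the livers of 6 mice. In 3 mice the innate immune adaptor Sting1, which relays the sensing of cytosolic DNA by cGAS, carried floxed alleles together with the endothelial Cre driver Cdh5-Cre, so that the gene is deleted in endothelial cells (endothelial Sting knockout). The other 3 mice were Cre-negative littermates with the same floxed alleles (control). All animals received a choline-deficient, amino acid-defined high-fat diet for 10 weeks from 8 weeks of age, a regimen that produces steatohepatitis and fibrosis. Total counts were 20414466, 18528915 and 19621497 in knockout replicates 1 to 3 and 19542060, 16704664 and 21025461 in control replicates 1 to 3. The comparison asks which liver transcripts differ between mice with and without the directed Sting1 deletion under this diet. Cre was present only in the knockout group, so that an effect of Cre itself cannot be told apart from that of the deletion. Whether cell types other than endothelial cells lost Sting1 was not measured.

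The labels name both whole liver and sinusoidal endothelial cells, and the values were those of whole liver. Albumin (Alb) alone took 9.81%, 9.60% and 10.9% of the counts in the knockout libraries and 9.07%, 6.91% and 9.61% in the control libraries. The TPM of Alb was 77400 ± 10300 (SD, n = 3) in control and 89900 ± 6340 (SD, n = 3) in knockout livers, whereas Pecam1, an endothelial adhesion molecule, stood at 26.1 ± 5.89 and 24.9 ± 1.43. Control replicate 2 stood apart from the other libraries. It had the lowest Alb share, a mean correlation with the others of 0.953 against 0.966 to 0.974 elsewhere, and a TMM factor of 1.26 against 0.922 to 1.01. The factors also separated the groups, at 0.922, 0.941 and 0.928 in knockout and 1.01, 1.26 and 0.975 in control replicates 1 to 3. TMM scaling therefore raised knockout CPM relative to control CPM.

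Sting1 (ENSMUSG00000024349, GRCm38 chromosome 18, 35733679 to 35740554, minus strand) was lower in every knockout library than in every control library. It had 106, 114 and 80 counts in the knockout and 240, 365 and 226 in the control libraries. The means were 5.53 ± 1.08 CPM (SD, n = 3) and 13.5 ± 3.40 CPM (SD, n = 3), so that the knockout livers held 40.9% of the control level. The log2 fold change was -1.29 with a standard error of 0.23. In edgeR's quasi-likelihood test its unadjusted p was 0.0004465, and its adjusted p over all genes was 0.357 with Benjamini-Hochberg adjustment. DESeq2's adjusted p was 0.00154. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. The deleted exon is not given in the sources used here, so that reads outside it can still be counted. The deletion was directed to endothelial cells and whole liver was sequenced, so that transcripts of other cell types can remain as well. The source of the remaining Sting1 was not tested.

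**Figure D1:**
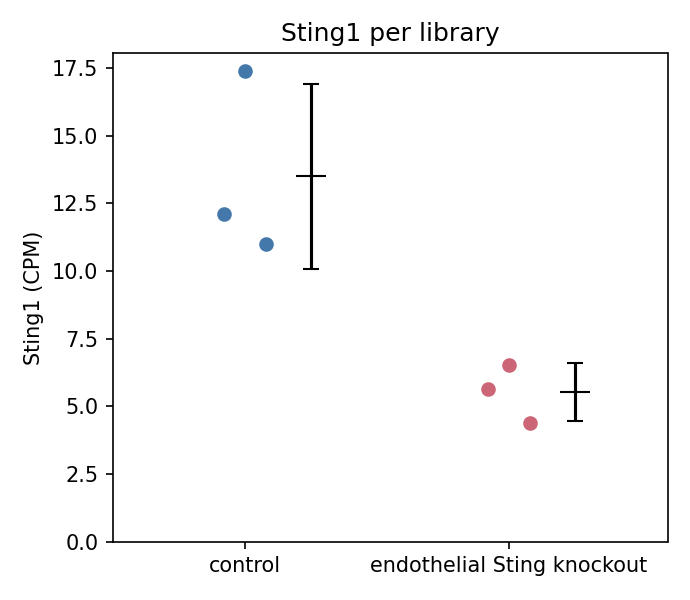
Sting1 in CPM (vertical axis) in the 3 control and 3 endothelial Sting knockout livers. Points are libraries and the bars beside them are the mean ± SD; the knockout mean of 5.53 lies below the control mean of 13.5 with no overlap of the libraries.

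No gene passed the genome-wide test. Of 13197 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.357. At an unadjusted p under 0.05 there were 1419 genes, 495 higher and 924 lower in the knockout, where 660 are expected by chance. The groups did not overlap for 2163 genes, 16.4% of those tested against the 10% that chance gives for 3 against 3. DESeq2 called 119 genes, 36 higher and 83 lower, and limma-voom called 0. Without control replicate 2, and also without control replicate 3, edgeR called 2 genes.

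The genes with the smallest p in each direction did not pass the test and are given with their values. Among the lower genes were regulators of mitosis: Ckap2, a spindle protein (log2 fold change -2.25, standard error 0.29), Nek2 (-1.32), Ccnb1, which encodes cyclin B1 (-1.66), Cdkn3 (-2.37), Knstrn (-1.48), Ect2 (-2.04) and Kif20a (-1.78). Ddit4, an inhibitor of mTORC1 signalling, stood at 15.8 ± 3.12 CPM (SD, n = 3) in control and 5.57 ± 0.92 CPM in knockout livers. Ccn2, a matricellular protein induced by TGF-beta and YAP, stood at 65.4 ± 22.3 and 20.9 ± 2.63 CPM. Trp53inp1, a p53 target, had a log2 fold change of -1.62. Among the higher genes were S1pr5, a sphingosine-1-phosphate receptor of natural killer cells (2.28, standard error 0.37), the leukocyte receptor Lilra5 (1.18), Il15ra, which presents interleukin 15 (1.02), Mtss1 (0.88), Sbk1 (1.21), Tedc2 (1.36), Zfhx2 (0.84), Gorasp1 (0.69), Hes6 (1.02) and the unnamed transcript Gm45140 (0.83). All 20 shared an adjusted p of 0.357 in edgeR with Benjamini-Hochberg adjustment.

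Proliferation genes were lower as a list, with the smallest camera p of the 40 gene lists fixed beforehand. Of 22 members 18 were below 0, with a median log2 fold change of -1.29 (camera adjusted p = 1.3e-13 with a preset correlation). With an estimated correlation the adjusted p was 0.68. None passed over all genes, and 15 passed when adjusted over the list alone, in edgeR's test. Cdc20, an activator of the anaphase-promoting complex, stood at 15.3 ± 6.99 CPM (SD, n = 3) in control and 4.89 ± 0.80 CPM in knockout livers, and Ccna2 and Kif11 had log2 fold changes of -1.38 and -1.61. Mki67 was at 22.4 ± 10.6 and 7.52 ± 4.54 CPM, with overlapping libraries. Without control replicate 2 the median was -0.81, and 8 members passed over the list alone; without knockout replicate 3, 8 passed, and without knockout replicate 1, 9.

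Matrix and bile duct genes were lower as lists. Of 30 extracellular matrix and fibrosis genes 28 were below 0, with a median of -0.72 (camera adjusted p = 2.2e-11). Of 15 cholangiocyte markers all 15 were below 0, with a median of -1.31 (camera adjusted p = 1.1e-09). Both had an adjusted p of 0.68 with an estimated correlation. Adjusted over the list alone in edgeR's test, 1 matrix gene passed, Ccn2, and 2 cholangiocyte markers passed, the chloride channel Cftr (-1.87) and the glucose transporter Slc5a1 (-1.31). Tgfb2, Lox, the collagen cross-linking enzyme, and Fstl1 had log2 fold changes of -1.21, -1.07 and -0.88 and did not pass. Control replicate 2 held the highest score for both lists, and without it the medians were -0.28 and -0.82. Control replicate 3 lay near the knockout libraries in the matrix score, at -0.242 against -0.298, -0.319 and -0.317. In the cholangiocyte score it lay below knockout replicate 1, at -0.077 against 0.218. The number of members passing over the list alone moved to 26 matrix genes without control replicate 3, and to 12 and 11 cholangiocyte markers without knockout replicate 1 and without control replicate 3. For cholangiocyte markers it was 0 without knockout replicate 2, knockout replicate 3 or control replicate 2, and 1 without control replicate 1.

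Stellate cell and myofibroblast markers had a median of -0.23, with 15 of 20 below 0 (camera adjusted p = 0.019). Capillarization and vascular endothelial genes had a median of -0.44, with 13 of 17 below 0 (camera adjusted p = 0.04). The adjusted p of both was 0.69 with an estimated correlation. Adjusted over the list alone in edgeR's test, Hgf, the hepatocyte growth factor made by stellate cells (-0.94), and Ngfr (-0.70) passed, and no member of the vascular list did. That stellate count of 2 was 0 without knockout replicate 2, knockout replicate 3, control replicate 1 or control replicate 2, and 1 without control replicate 3. Lamb1, a basement membrane laminin chain, had a log2 fold change of -0.53. Neither list kept its call in all leave-one-out fits: the vascular median was -0.0995 without control replicate 2 and -0.36 without knockout replicate 2, and the stellate median was -0.18, -0.19 and -0.18 without knockout replicate 2, knockout replicate 3 and control replicate 1.

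Markers of resident macrophages and of T and natural killer cells were higher as lists. All 18 Kupffer cell markers were above 0, with a median of 0.56 (camera adjusted p = 6.6e-10). Of 22 T and natural killer cell markers 18 were above 0, with a median of 0.56 (camera adjusted p = 8.7e-06). Each had an adjusted p of 0.68 with an estimated correlation. Summed CPM before TMM scaling overlapped between the groups for both lists. It was 1590 ± 322 (SD, n = 3) in control and 1850 ± 193 in knockout livers for Kupffer cell markers. For T and natural killer cell markers it was 40.9 ± 9.67 and 58.8 ± 16.7. Cd5l, a secreted Kupffer cell protein, stood at 241.5 ± 60.8 CPM (SD, n = 3) in control and 372.9 ± 51.0 CPM in knockout livers. No Kupffer marker passed over the list alone, whereas 7 T cell markers did in edgeR's test, among them Cd8a (1.64), Tox (0.93) and the checkpoint receptor Pdcd1 (1.33). That count of 7 was 0 without knockout replicate 1 and without each control replicate, and 1 without knockout replicate 2. The median was 0.28 without knockout replicate 1.

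Endothelial markers were higher in the scaled fit and not in summed counts. Sinusoidal endothelial markers had a median of 0.25, with 14 of 22 above 0 (camera adjusted p = 0.0046), and pan-endothelial markers a median of 0.19, with 16 of 20 above 0 (camera adjusted p = 0.027). These calls ended with an estimated correlation, at an adjusted p of 0.68 for both. Gpr182, a sinusoidal scavenger receptor, had a log2 fold change of 0.61 and Cldn5 one of 0.56; neither passed. The summed CPM of the sinusoidal list, before TMM scaling, was 2650 ± 204 (SD, n = 3) in control and 2290 ± 106 in knockout livers, so that the direction differed from that of the median. Both medians lay below 0 in log2(TPM + 1), where the median of all genes shifted by -0.20, and above 0 relative to that shift. The sinusoidal call was lost without control replicate 2, with a median of 0.25, and the pan-endothelial call without knockout replicate 1 and without control replicate 1, with medians of 0.11 and 0.12.

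Interferon lists moved little. Of 27 genes of the interferon-gamma and antigen presentation list 24 were above 0, with a median of 0.26 (camera adjusted p = 0.0011), and of 33 type I interferon response genes 19 were above 0, with a median of 0.12 (camera adjusted p = 0.045). With an estimated correlation the adjusted p was 0.68 and 0.78. Irf1 had a log2 fold change of 0.57 and Zbp1 one of 0.60, and no member passed over either list alone. The type I median turned to -0.04 without knockout replicate 2 and to -0.02 without control replicate 3, and lost its call without control replicate 1 at 0.07. In log2(TPM + 1) it was -0.124, and 0.0735 relative to the shift of all genes. The interferon-gamma call was lost without knockout replicate 1 and without control replicate 3, with medians of 0.15 and 0.14. In log2(TPM + 1) the interferon-gamma median was 0.00354, and 0.201 relative to the shift of all genes. The other cGAS and STING pathway components had a median of 0.07 (camera adjusted p = 0.41), with 11 of 19 above 0. NF-kB target cytokines and chemokines had a median of -0.00888 (camera adjusted p = 0.43), although the mean lay above 0; of these Ccl5, a T cell chemokine, passed over the list alone (1.15). Endothelial leukocyte adhesion genes had a median of -0.03 (camera adjusted p = 0.68).

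Hepatocyte lists were higher. Lipogenesis genes had a median of 0.51, with 19 of 22 above 0 (camera adjusted p = 4.1e-05), cholesterol synthesis genes 0.41, with 24 of 25 above 0 (camera adjusted p = 0.00014), and acute-phase genes 0.40, with 22 of 23 above 0 (camera adjusted p = 3.8e-07). Pericentral genes had a median of 0.43 (camera adjusted p = 1.5e-05), hepatocyte identity genes 0.35 (0.0066), xenobiotic metabolism genes 0.30 (0.0091), bile acid genes 0.31 (0.046), male-biased genes 0.56 (0.019) and nuclear-encoded oxidative phosphorylation genes 0.18 (0.0016). With an estimated correlation the adjusted p was 0.68 for lipogenesis, acute-phase and xenobiotic genes and 0.69 for the others. No member of these lists passed over the list alone. Dgat2, which makes triglyceride, and Saa2, an acute-phase apolipoprotein, had log2 fold changes of 0.69 and 0.97. Over the fits that leave out 1 library the median ran from 0.307 to 0.633 for lipogenesis, 0.174 to 0.786 for cholesterol synthesis and 0.313 to 0.458 for acute-phase genes. Without control replicate 2 the calls for cholesterol synthesis (0.20), pericentral (0.11), hepatocyte identity (0.15), xenobiotic (0.03), bile acid (0.04), male-biased (0.17) and oxidative phosphorylation genes (0.07) were lost. Without knockout replicate 3 those for cholesterol synthesis (0.17), hepatocyte identity (0.28) and oxidative phosphorylation (0.07) were lost, without knockout replicate 1 that for bile acid genes (0.20), and without knockout replicate 2 that for male-biased genes (0.36). The oxidative phosphorylation median was -0.0567 in log2(TPM + 1), and 0.141 relative to the shift of all genes. The other medians of these lists stayed above 0 in log2(TPM + 1). Hepatocyte identity stood there at 0.102 and xenobiotic genes at 0.0873, and at 0.3 and 0.285 relative to the shift.

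Circadian genes moved in opposite directions. Of 18 clock genes 13 were above 0, with a median of 0.56 (camera adjusted p = 0.00071), and with an estimated correlation the adjusted p was 0.68. Adjusted over the list alone in edgeR's test 7 genes passed as higher and 2 as lower. Cry2 (0.84), Ciart (2.28) and Tef (1.05) were higher, and the core activators Bmal1 (-0.91) and Clock (-0.63) were lower. Without knockout replicate 3 none passed over the list alone, and the median was 0.33. The count of lower genes was also 0 without each control replicate in turn, and that of higher genes was 5 without knockout replicate 1, 2 without control replicate 2 and 3 without control replicate 3.

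**Figure D2:**
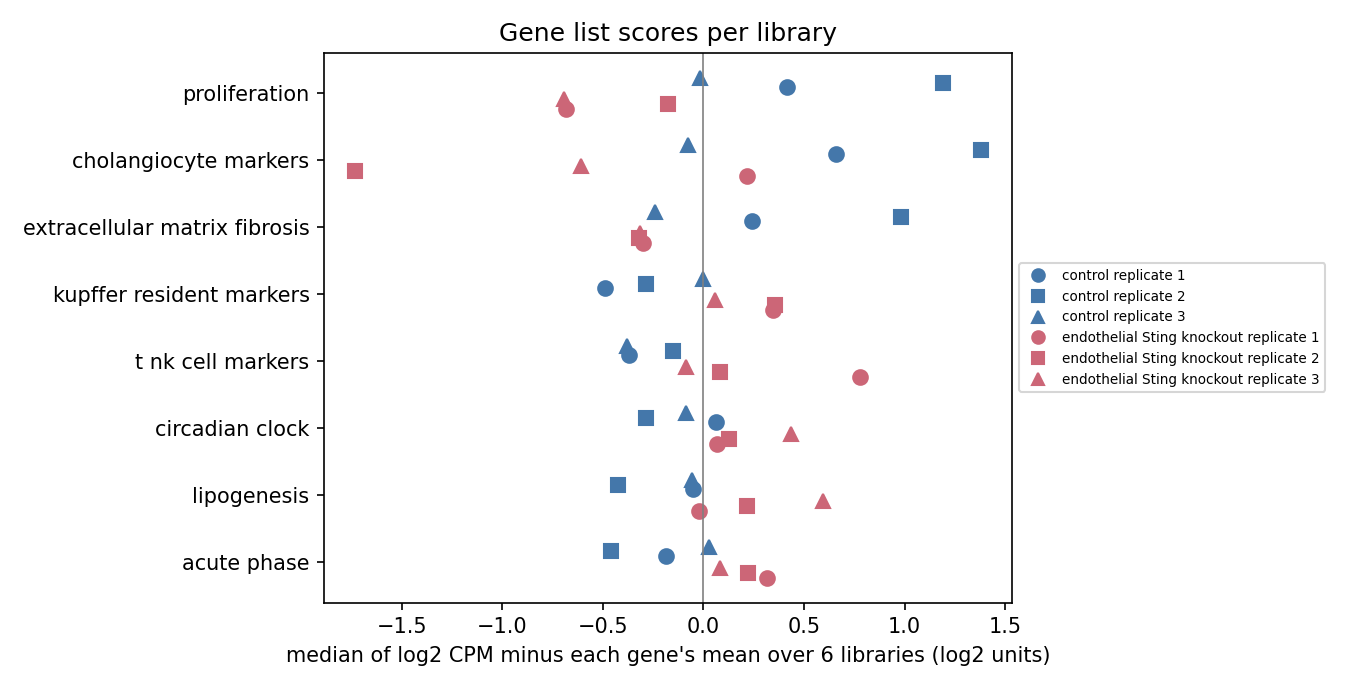
Scores of 8 gene lists (rows) per library, as the median over members of log2 CPM minus each gene's mean over the 6 libraries (horizontal axis, log2 units). Blue marks are control and red marks knockout livers, with a symbol per replicate; control replicate 2 has the highest proliferation, cholangiocyte and matrix scores.

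The remaining lists were not called by camera. Neutrophil markers had a median of 0.89 (adjusted p = 0.076), B and plasma cell markers 0.26 (0.16), dendritic cell markers -0.14 (0.37), and monocyte and lipid-associated macrophage markers 0.01 (0.65). Periportal genes had a median of 0.32 (0.062), PPAR-alpha and fatty acid oxidation genes 0.14 (0.56), lipid droplet and uptake genes 0.09 (0.47), female-biased genes -0.35 (0.80), endoplasmic reticulum stress genes 0.32 (0.099), cell death and inflammasome genes 0.04 (0.65), and NRF2 antioxidant genes -0.02 (0.43). Immediate early genes had a median of -0.07 (0.25), erythroid genes -0.41 (0.56), mitochondrial genome transcripts 0.03 (0.79), ribosomal protein genes 0.07 (0.27), and 2 tested genes of neighbouring tissue 0.59 (0.16). Some of these lists were called by camera when a library was left out: neutrophil markers without knockout replicate 2 (median 1.28), knockout replicate 3 (1.34) or control replicate 2 (1.03), B and plasma cell markers without knockout replicate 3 (0.43), and stress genes without knockout replicate 1 (0.60). Without knockout replicate 2, periportal (0.45), lipid droplet (0.17) and immediate early genes (-0.22) were called. PPAR-alpha genes were called lower without knockout replicate 1 (-0.09) and higher without knockout replicate 2 (0.29). Adjusted over the list alone in edgeR's test, Igfbp1, an insulin-repressed hepatocyte gene of the periportal list (-1.71), and the death receptor Tnfrsf10b (-1.48) passed. The cell death list had an adjusted p of 0.0091 in fry's test of change in either direction.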

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

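The fit without control replicate 2 and camera on annotation terms were chosen after seeing the data. Sting1 was lower under every alternative run, with log2 fold changes from -1.42 to -1.04. The count of genes passing edgeR's adjusted test stayed at 0 under both other scalings, both other filters, limma-voom with and without weights, a 2-fold minimum and both TPM fits. It was 119 in DESeq2 and ranged from 0 to 2 over the fits that leave out 1 library. Genes at an unadjusted p under 0.05 ranged from 325 to 596 higher and from 487 to 1162 lower over those fits. In log2(TPM + 1) they were 115 higher and 1441 lower, and in log2(TPM + 0.1) 114 and 1478; the shift of all genes by -0.20 in TPM moves that split. The replicate numbers showed no clear pairing of the samples. Deviations of same-numbered libraries correlated at 0.11, -0.0068 and 0.13, and those of other pairs ran from -0.28 to 0.18. So few values cannot exclude a pairing. With a replicate block 5 genes passed, 785 were higher at an unadjusted p under 0.05, and the adhesion list's median was 0.00109. Camera called 22 lists with the block, 20 of them as in the main fit. Over the list alone 0 cholangiocyte, 3 T and natural killer cell, 1 stellate and 3 matrix members then passed. For proliferation 16 passed, and for clock genes 9 passed as higher and 3 as lower. Not every sample correlated best with its own number: knockout replicate 3 did, and knockout replicates 1 and 2 correlated best with control replicates 2 and 3.

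Camera called 21 lists, 0 with an estimated correlation and 0 in fry, and from 13 to 22 over the fits that leave out 1 library, with 13 without control replicate 2. Of these 8 lists kept their call in all 6 such fits. Annotation terms were not tested for edgeR's calls; they numbered 12 for DESeq2's calls and 156 for camera with the preset correlation, against 0 with an estimated one. The summed pan-endothelial markers were 261 in TPM. The NF-kB median turned to 0.00071 with DESeq2's size factors. Medians that changed sign over the fits that leave out 1 library ranged as follows. They ran from -0.0235 to 0.12 for cGAS and STING components, -0.0432 to 0.266 for type I interferon, -0.135 to 0.152 for NF-kB and -0.0618 to 0.0918 for adhesion genes. They ran from -0.146 to 0.217 for monocyte and lipid-associated macrophage, -0.262 to 1.34 for neutrophil, -0.0191 to 0.432 for B cell and -0.304 to 0.052 for dendritic cell markers. For PPAR-alpha genes they ran from -0.0943 to 0.288, lipid droplet genes -0.141 to 0.169, female-biased genes -0.46 to 0.704 and endoplasmic reticulum stress genes -0.144 to 0.605. For cell death genes they ran from -0.0138 to 0.119, NRF2 genes -0.0751 to 0.109, immediate early genes -0.219 to 0.093 and erythroid genes -0.652 to 0.0782. Mitochondrial genome transcripts ran from -0.101 to 0.199 and ribosomal protein genes from -0.0248 to 0.143. The cause of these changes was not tested. Depth was alike across libraries, and Sting1 rested on 80 to 365 counts.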

Other observations

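All tests in this part were chosen after the result was seen, except those of corticosteroid-induced genes, of p53 targets and of other splits of the libraries. A set of 15 mitotic genes, all from the proliferation list already seen to be lower, had a score lower by -1.39 (standard error 0.391), with all 15 below 0, whereas 14 genes of DNA replication licensing and synthesis differed by 0.0439 (standard error 0.0985), with 8 above 0 and 6 below. Of those 14 genes 8 belong to no list fixed beforehand, and the difference between the sets was not tested. Among annotation terms, complement and coagulation cascades (median 0.324) and mitochondrial translation (0.165) were called higher by camera with the preset correlation and ECM-receptor interaction (-0.484) lower, and all 3 had an adjusted p of 0.92 with an estimated correlation. The Y-linked genes Ddx3y and Uty had log2 fold changes of -0.57 and -0.44 and did not pass, whereas the median of their male-biased list was 0.56. Ddx3y ran from 11.2 to 27.9 TPM and the Y-linked Eif2s3y from 25.5 to 40.6 TPM, so that every library held Y-linked transcripts.

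Other splits of the 6 libraries bear on how much weight the list calls carry. The knockout and control grouping gave 1419 genes at an unadjusted p under 0.05 and another grouping gave 1404; only 1 of the 10 splits, the real one, gave as many. Camera with the preset correlation called 21 lists for the real grouping and up to 22 for others, and 4 of the 10 splits called at least as many. DESeq2 called 119 genes for the real grouping and 213 for the split of knockout replicate 1 and control replicates 1 and 2 against the rest. Where the calls of that split come from was not tested. Since 10 splits cannot give a share under 0.05, no more can be said from them.

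Clock genes differed between the groups. The score of 8 genes that peak by day minus that of 5 that peak around dawn was higher by 1.88 in the knockout (standard error 0.623), with no overlap of the libraries. Livers collected at a different time of day may account for this, since the sets moved in opposite directions. All but 1 of the 13 genes had been seen in the clock list, so the test adds little that is independent. A change of the clock by genotype predicts the same values, and collection times were not used here, so that both stay open.

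Matrix, cholangiocyte and proliferation genes were lower in the knockout. Control replicate 2 alone could give part of the difference: without it the medians were nearer to 0, and the nearest was -0.279, neither within 0.2 of 0 nor below -0.4. A lower share of all non-parenchymal cells as the whole cause was not decided, because the lists used to test it were picked from values already seen. That explanation predicts that the sinusoidal, pan-endothelial, Kupffer cell and T cell lists fall too. These 4 lists were chosen after they had been seen to be higher. With TMM scaling 4 of these 4 were above 0 by more than 2 standard errors between libraries, and 3 were in TPM relative to each library's median over all genes, against 0 in TPM as deposited, where all genes shift by -0.20. These measures were changed after values had been seen, and the reading with them. The spread between genes went against the explanation, TPM as deposited left it open, and TMM scaling and relative TPM went against it again. Lists picked for being higher cannot decide it. Relative to the matrix score, which needs no scaling, 3 of the 4 were above by more than 2 standard errors. The Kupffer cell score was higher by 1.15 (standard error 0.452) and the sinusoidal score by 0.836 (standard error 0.436). The matrix list had been seen to be lower and the 4 lists higher. A difference above 0 was therefore set by the choice of lists and adds no support. Other non-parenchymal values go with a lower share: the vascular endothelial median was -0.44, the stellate median -0.23 and the dendritic cell median -0.14. Summed sinusoidal CPM was also lower in every knockout library than in every control library. The neutrophil and B cell medians went the other way, at 0.89 and 0.26, and the monocyte median was 0.01. A lower share of all non-parenchymal cells, or of single cell types, stays open. A difference by genotype stays open as well: every knockout library lay below every control library for 2 of the 3 lists, which had been seen to be lower, so that this decides nothing.

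Igfbp1, Ddit4, Cdkn1a, Trp53inp1 and Sgk1, genes regulated by feeding, by hormones or by p53, were lower in the knockout, with log2 fold changes of -1.71, -1.50, -1.28, -1.62 and -0.85. Lower corticosteroid exposure at collection stays open. The score of 7 other corticosteroid-induced genes was lower by -0.427 (standard error 0.117) with no overlap, but 2 of the 7 belong to lists fixed beforehand, and the score of the other 5, a test chosen after the result was seen, differed by 0.0975 (standard error 0.228), with 3 of the 5 genes below 0. The values met the prediction written before they were seen, and only this added test leaves the explanation open. A more fed state stays open too. The score of fasting-induced minus feeding-induced genes was lower by -1.22 (standard error 0.439) with no overlap, as it predicts, but the feeding-induced genes belong to the lipogenesis list already seen. Of the 10 fasting-induced genes 7 also belong to lists fixed beforehand, so that their score is not independent either. The fasting-induced score differed by -0.327 (standard error 0.226), past the bound of -0.3 set for it but within 2 standard errors of 0 and with overlapping libraries. That overlap was made a criterion after the value was seen, and without it the values meet the prediction. Lower p53 activity was not decided either. The score of 12 other targets was lower by -0.21 (standard error 0.0562) with no overlap. For the 11 outside the fixed lists it was -0.228 (standard error 0.0601), also with no overlap. Neither reached the bound of -0.3 set for it, which lay within 2 standard errors of both. Among the terms of DESeq2's lower calls was the p53 signaling pathway, with 5 called genes (Fisher's exact test, adjusted p = 0.0222). Those lower calls include Cdkn1a and Trp53inp1 of this pattern and Ccnb1 and Ccnb2 of the proliferation list, all already seen to be lower. The term therefore adds no independent support. Other biological differences by genotype were not tested for these genes and stay open.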
